A study of Mus musculus with 12 samples.

How the data were processed

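RNA from the medial prefrontal cortex (mPFC) of wild-type male mice was sequenced 4 weeks after chronic constriction injury (CCI) of the left sciatic nerve, or from naive mice. There were 4 libraries of the left mPFC of CCI mice (ipsilateral to the nerve), 4 libraries of the right mPFC of CCI mice (contralateral) and 4 libraries of naive mice, whose hemisphere the labels do not give. The library codes of the CCI samples hold a number and the letter L or R, and left and right libraries with one number were read as the hemispheres of one mouse; the labels do not say this outright.

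The authors deposited one table with raw counts per gene and library, and beside them FPKM values that the authors scaled by gene length and by the total of the counts. Among genes with high enough counts to check, count divided by FPKM followed one factor per library within a relative departure of 8.96e-06. For these genes FPKM holds no information beyond the counts, and it was not tested. Genes of low counts were not checked in this way. A second deposited table repeats the genes with other text annotation, the GO term and KEGG pathway names of each gene, which was used to group genes; its source and date are not stated. The submitters' processing notes name HISAT2 2.0.4 and GRCm38/mm10 without saying what each was used for, and per the labels the libraries were made with an mRNA kit. The counting program and the annotation release are not given in the sources used here. Coordinates are those of the deposited table. Every per-sample column was matched to a library. The table holds 34745 genes, of which 11491 had a count of 0 in every library. Of the gene symbols, 27 had been changed into dates and 67 occurred more than once, so genes were handled by their Ensembl identifier.

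Total counts ranged from 16.1 to 20.6 M (mega-counts) per library. Differences were tested with edgeR 4.0.16 in R 4.3.3 on the counts, with TMM factors, the filterByExpr filter by group and robust quasi-likelihood fits; limma 3.58.1 and DESeq2 1.42.0 served the other tests. All 12 libraries entered a fit with 3 groups and 15808 tested genes, which gave contralateral against naive, ipsilateral against naive, and contralateral against ipsilateral. In a second fit the counts of both hemispheres of each CCI mouse were summed, which gave 1 value for each of 8 mice and 16179 tested genes. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. Values per library are CPM with TMM factors, and errors of log2 fold changes are standard errors (SE), taken from the fold change and its F statistic.

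Gene lists were compared with all other tested genes by camera with a preset correlation between genes of 0.01, adjusted over all lists and comparisons together (128 tests). Beside it stood camera with an estimated correlation, and fry, which tests whether the genes of a list move one way (directional) or in either way (mixed). The 32 lists were immediate early genes; excitatory neuron, inhibitory interneuron, microglia, astrocyte, oligodendrocyte and myelin, oligodendrocyte precursor, endothelial, mural, meningeal and fibroblast, choroid plexus and ependyma, blood cell, striatum and olfactory markers; GABA, glutamate, and monoamine and acetylcholine receptors; voltage-gated ion channels; opioid and endocannabinoid genes; neurotrophic factors; synaptic vesicle and scaffold genes; cytokines; interferon response and antigen presentation, glucocorticoid response, circadian clock, heat shock, perineuronal net, DNA methylation and histone deacetylase, oxidative phosphorylation, cytosolic ribosomal protein, mitochondrially encoded, and sex-linked genes. Some genes stand on more than one list, among them Drd1 and Drd2 (striatum and monoamine receptors), Penk (striatum and opioid) and Slc32a1 (striatum and interneurons). GO and KEGG terms with 15 to 300 tested genes were tested by camera and adjusted within each comparison. A score per library, the mean over a list's genes of the log2 CPM centred on each gene's mean (prior count 2), was compared between groups by exact permutation over 70 arrangements, for which the smallest two-sided p is 0.0286.

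The comparisons, tests, lists, alternatives and the rule for naming genes were set before the data were examined; later choices are named as such. The rule names, per comparison, up to 10 higher and 10 lower genes past the threshold; with fewer than 12 passing, the genes of smallest unadjusted p up to 12, predicted models left out; per list its members past the threshold (at most 4), else up to 3 of smallest unadjusted p; and always Gad1, Pvalb, Sst, Vip, Fos, Arc, Bdnf, Gfap, Aif1, Oprm1, Fkbp5 and Mbp. Some genes that the rule names are not reported here. The alternatives were other scaling factors, filters and tools, fits of only the groups compared, a block for the replicate number, a cell type score as covariate, and leaving out each library or mouse in turn.

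The reading of left and right libraries as pairs was checked on the counts. Across genes, the residuals of left and right libraries with one number correlated by 0.012, -0.137, 0.038 and 0.060, and the consensus correlation from duplicateCorrelation was -0.0233, so that most genes gave no sign of a shared mouse. Of the 24 ways to pair left with right libraries, the coded one had the smallest summed difference of immediate early gene scores (0.291, next 0.564), a check added after seeing the data. The naive libraries, which are of other mice, took the same order by number, so this check cannot show that left and right came from one mouse, and the pairing rests on the library codes alone. A mouse block left contralateral against ipsilateral at 0 genes. No pair of libraries was a copy of another (chi-square per degree of freedom between libraries 9.15 to 33.0).

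The procedure was tested on simulated data with the spread of these libraries, with 100 genes changed by 1.5-fold and 100 by 2-fold in each comparison. The changed genes were drawn from those above a low average level, astrocyte markers were shifted as well, and genes varied independently of one another. Contralateral against naive recovered 66% of 1.5-fold and 91% of 2-fold changes (15685 genes). The shares were 65% and 88% for ipsilateral against naive (15697 genes), 66% and 94% for contralateral against ipsilateral (15693 genes), and 78% and 97% for the 8 mice (15788 genes). Between 6 and 16 unchanged genes were called per comparison. With so many changes at once the adjusted threshold is more lenient than with few. The shares therefore do not tell how many changes of these sizes would be found in the real data.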

Results

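Transcript levels were measured by RNA sequencing in the mPFC, a cortical region that takes part in the affective side of pain, of mice with a constricted sciatic nerve and of naive mice. The 12 libraries fell into 3 groups of 4, the left (ipsilateral) and the right (contralateral) mPFC of CCI mice and the mPFC of naive mice. Total counts averaged 18.5 ± 1.47 M (mega-counts) in ipsilateral, 17.4 ± 0.86 M in contralateral and 17.2 ± 0.47 M in naive libraries (SD, n = 4 each). Mitochondrially encoded genes took 7.31 ± 0.19%, 8.0 ± 1.16% and 7.67 ± 0.54% of the counts.

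The first question was how the mPFC opposite to the injured nerve differed from that of naive mice. Wdfy1 (ENSMUSG00000073643; chromosome 1, 79702262 to 79776143, GRCm38/mm10), which encodes an endosomal adaptor protein, had the smallest p: its level was 44.5 ± 9.4 CPM in contralateral and 21.9 ± 1.4 CPM in naive libraries (SD, n = 4 each), a log2 fold change of 1.02 (SE 0.15). Tmem260 (ENSMUSG00000036339; chromosome 14, 48446128 to 48515135) stood at -0.99 (SE 0.18) and Abi3bp (ENSMUSG00000035258; chromosome 16, 56477846 to 56690128), an extracellular matrix protein gene, at -1.01 (SE 0.21). None of these passed in the main edgeR fit (adjusted p = 0.206 for Wdfy1, 0.811 for Tmem260 and 1.00 for Abi3bp). The 22 genes of oligodendrocytes and myelin all had a positive fold change (median 0.29; camera adjusted p = 0.00596, but adjusted p = 0.823 with an estimated correlation), carried by contralateral 1 and 2 (scores 0.52 and 0.68) and not by contralateral 3 and 4 (-0.35 and -0.47). Of 16 genes of GABA receptors and their scaffold, 15 had a negative one (median -0.06; camera adjusted p = 0.00496, but adjusted p = 0.723 with an estimated correlation).

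The other genes of smallest p in this comparison had log2 fold changes of -0.93 (Klhl14), -0.45 (Lmbr1), -0.31 (Lmo7), -0.32 (Sh3kbp1), 0.38 (Sfi1), -0.44 (Brinp3), -0.40 (Fbxw7, a ubiquitin ligase subunit), 0.88 (Zmym1) and -0.47 (Zfp189), and none passed. Among the genes fixed for every comparison, the µ-opioid receptor gene Oprm1 stood at -1.05 (SE 0.57) at a level of 1.02 CPM or less in every library, the astrocyte filament gene Gfap at 0.41 (SE 0.37) and the myelin gene Mbp at 0.22. The interneuron genes Gad1 (-0.09), Pvalb (-0.15), Sst (0.07) and Vip (0.07) lay near 0, as did Bdnf (-0.03), Aif1 (0.05) and Fkbp5 (0.03). The activity-regulated genes Fos (0.15, SE 0.65) and Arc (0.02, SE 0.67) varied too widely between mice for a difference of this size to be detectable in this fit. The fit has no block for the replicate number, with which the levels of both genes rose in contralateral and in naive libraries.

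In list tests, camera called 6 of the 32 lists for the contralateral side against naive. Cytosolic ribosomal protein genes (70 of 81 members positive; adjusted p = 2.98e-06), oligodendrocyte and myelin genes (0.00596), oligodendrocyte precursor markers (13 of 14 positive; 0.00896), glucocorticoid response genes (15 of 18 positive; 0.0227) and microglia markers (17 of 22 positive; 0.0299) were higher, and GABA receptors lower (0.00496). None of the 6 held, with adjusted p = 0.723 to 0.823 with an estimated correlation. Examples, none past the threshold alone, were Apod (0.54) for myelin, the glucocorticoid-induced Zbtb16 (0.19) and Tsc22d3 (0.25), and Nlgn2 (-0.19), the neuroligin of inhibitory synapses. The GO term cytosolic ribosome was called as higher (camera adjusted p = 0.0279, and adjusted p = 0.977 with an estimated correlation), the only one of 4154 terms.

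No gene passed in edgeR for contralateral against naive (0 of 15808), nor with limma voom (0), while DESeq2 called 3, Wdfy1, Tmem260 and Abi3bp. At an unadjusted p under 0.05 there were 597 genes, 303 higher and 294 lower, against 790.4 that uniform p values give. The count became 1 without contralateral 2, 2 without contralateral 4 and 1 without naive 3, and the lists called became 10 without contralateral 1, 12 without contralateral 2 and 10 without naive 1.

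**Figure D1:**
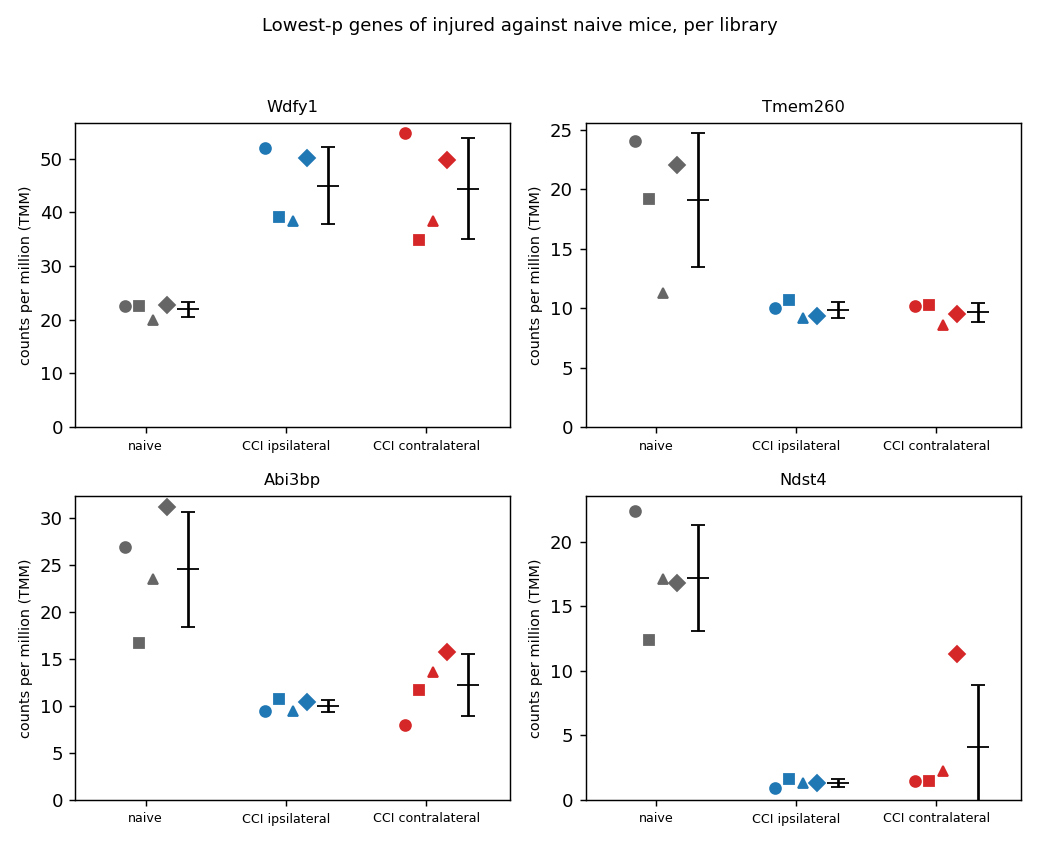
Levels of Wdfy1, Tmem260, Abi3bp and Ndst4 in each library, in CPM with TMM factors, by group; the marker's shape gives the replicate number (1 to 4 as circle, square, triangle and diamond) and bars give the mean ± SD. All 8 CCI libraries lie at 34.8 to 54.9 CPM of Wdfy1, above the naive libraries at 19.9 to 22.8 CPM; the SD bar of Ndst4 in contralateral libraries reaches below 0 and stops at the axis.

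The mPFC on the side of the injured nerve was compared with naive cortex in the same way. Wdfy1 was again at the top, at 44.9 ± 7.2 CPM in ipsilateral against 21.9 ± 1.4 CPM in naive libraries (SD, n = 4 each), a log2 fold change of 1.03 (SE 0.15). Abi3bp (-1.29, SE 0.21) and Tmem260 (-0.96, SE 0.18) followed. Ndst4 (ENSMUSG00000027971; chromosome 3, 125404076 to 125728899), an enzyme of heparan sulfate synthesis, had the widest difference of the named genes, -3.73 (SE 0.66): 0.91 to 1.65 CPM in the 4 ipsilateral libraries against 12.4 to 22.4 CPM in the naive ones. All 17 measured markers of meninges and fibroblasts had a negative fold change (median -0.45), and camera called them lower, along with markers of blood, vessel walls, astrocytes and microglia. None of these list calls held (adjusted p = 0.723 to 0.823 with an estimated correlation), and ipsilateral 2 stood apart from the other ipsilateral libraries with a meningeal score of 0.19.

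None of these genes passed in the main edgeR fit (adjusted p = 0.178 for Wdfy1, 0.339 for Abi3bp and 0.497 for both Tmem260 and Ndst4). In the edgeR fit of the 2 compared groups alone, Ndst4 (adjusted p = 4.7e-05), Wdfy1 (0.00335) and Abi3bp (0.0496) passed, but not Tmem260. With a block for the replicate number, Wdfy1 and Ndst4 passed in edgeR (adjusted p = 0.00744 for both). The remaining genes of smallest p had log2 fold changes of -0.34 (Pex5, the peroxisomal import receptor), -0.55 (Pds5a, a cohesin regulator), -0.42 (Mdga1), -0.35 (Lmo7), 0.54 (Cst6), -0.58 (Zfp189), 0.97 (Rsrc1) and -0.26 (Tmem35). Gad1 stood at 0.13, Pvalb at 0.35, Sst at 0.09, Vip at -0.21, Gfap at -0.62 (SE 0.38), Mbp at 0.09, Aif1 at 0.02, Bdnf at -0.08, Oprm1 at -0.31, Fkbp5 at -0.03, Fos at 0.12 and Arc at -0.04. Adjusted over the list alone, 3 genes passed: Dlx6os1 (-0.35) of the interneuron list, the nociceptin receptor gene Oprl1 (0.46) of the opioid list and the GDNF co-receptor gene Gfra1 (-0.28) of the neurotrophic list; over all genes tested, 0 list members passed.

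Camera called 9 lists for the ipsilateral side against naive. Lower were meningeal and fibroblast markers (adjusted p = 2.98e-06), blood cell genes (8 of 8 members negative; 0.00197), microglia (19 of 22; 0.00496), mural cell (12 of 13; 0.00886), astrocyte (17 of 20; 0.00896) and endothelial markers (15 of 18; 0.0260), and interferon response and antigen presentation genes (20 of 24; 0.0301). Higher were oxidative phosphorylation genes (62 of 81 positive; 0.0148) and voltage-gated ion channels (26 of 34 positive; 0.0227). All 9 calls were lost, with adjusted p = 0.723 to 0.823 with an estimated correlation. Examples were Fmod (-1.23) and Slc6a13 (-0.84) for meninges and fibroblasts, the water channel gene Aqp4 (-0.36) and Id4 (-0.33) for astrocytes, and Olfml3 (-0.46) and the complement gene C1qb (-0.24) for microglia; none passed alone. The meningeal score was between -0.60 and -0.49 in ipsilateral 1, 3 and 4, 0.19 in ipsilateral 2, and between 0.06 and 0.64 in the naive libraries.

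For ipsilateral against naive the edgeR count was 0 of 15808 genes, limma voom gave 0 and DESeq2 9, among them Wdfy1, Abi3bp, Tmem260, Ndst4, Rsrc1, Pds5a, Pex5 and Lmo7. There were 763 genes at an unadjusted p under 0.05 (295 higher, 468 lower, against 790.4 with uniform p values). The count became 1 without ipsilateral 4 and 1 without naive 3.

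Contralateral and ipsilateral cortex of the same CCI mice were set against each other to ask whether the hemispheres differed. Microglia markers were higher on the contralateral side in all 22 measured members, with a median log2 fold change of 0.19, and astrocyte markers in 19 of 20 (0.15). Meningeal and fibroblast markers were higher in all 17 (0.54), and voltage-gated ion channels lower in 27 of 34 (-0.15). None of these list calls held, with adjusted p = 0.723 to 0.820 with an estimated correlation, and no single gene passed. Mouse 2 went the other way in all 4 lists, with right minus left scores of -0.04 for microglia, -0.18 for astrocytes, -1.13 for meninges and 0.03 for channels. Of all 16 lists called between the sides, mouse 2 turned against mice 1, 3 and 4 in 8, the other 4 being mural markers (-0.42), blood cell (-0.29), interferon response (-0.02) and oxidative phosphorylation genes (0.06). It went the same way in 5, GABA receptors (-0.07), synaptic vesicle and scaffold genes (-0.03), precursor (0.02) and striatum markers (0.03) and ribosomal protein genes (0.00). In the remaining 3, endothelial markers, mitochondrially encoded genes and monoamine and acetylcholine receptors, mice 1, 3 and 4 differed in sign.

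The genes of smallest p were higher on the contralateral side for Tbx15 (1.49, SE 0.30, at less than 1 CPM in every library), Dnah7b (0.71), Efs (0.56), Mfge8 (0.56, SE 0.12), whose product marks dying cells for phagocytosis, Elmo3 (1.14), Megf6 (0.62) and the sodium channel subunit gene Scn3b (0.43). They were lower for Fbxw7 (-0.45), the neuronal enolase gene Eno2 (-0.26) and St8sia1 (-0.32). For each of these genes the edgeR adjusted p was 0.592, the smallest of the comparison. Gad1 stood at -0.21, Pvalb at -0.50, Vip at 0.28 and Gfap at 1.04 (SE 0.38). Adjusted over the list alone, genes that passed included Scn3b (against the direction of its list), the astrocyte genes Id4 (0.43) and Gja1 (0.28), and the precursor genes C1ql1 (0.45) and Vcan (0.36), while over all genes tested 0 list members did.

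Camera called 16 lists between the sides. Higher on the contralateral side were cytosolic ribosomal protein genes (70 of 81 positive; adjusted p = 3.65e-06), microglia (3.65e-06), astrocyte (0.000102), precursor (13 of 14; 0.000780), mural (12 of 13; 0.00160), meningeal (0.00160) and endothelial markers (17 of 18; 0.00541), blood cell genes (8 of 8; 0.0204), mitochondrially encoded genes (13 of 13; 0.0274), interferon response genes (20 of 24; 0.0301) and striatum markers (13 of 15; 0.0330). Lower were voltage-gated ion channels (0.000476), oxidative phosphorylation genes (65 of 81 negative; 0.000573), GABA receptors (12 of 16; 0.00541), synaptic vesicle and scaffold genes (23 of 30; 0.00702) and monoamine and acetylcholine receptors (18 of 30; 0.0207). None held, with adjusted p = 0.723 to 0.823 with an estimated correlation. Examples, none past the threshold over all genes, were C1qc (0.31), Cx3cr1 (0.28), Aqp4 (0.31), Fabp7 (0.76), Myl9 (0.67) and Rps2 (0.23), and on the other side Syn1 (-0.15), Ndufb5 (-0.30) and Nlgn2 (-0.18). The striatum list was carried by contralateral 1, whose score was 1.21 against -0.19 to 0.07 in all other libraries. In that library Adora2a was at 15.2 CPM and Drd2 at 8.77 CPM, and without it the list was no longer called (adjusted p = 0.977).

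**Figure D2:**
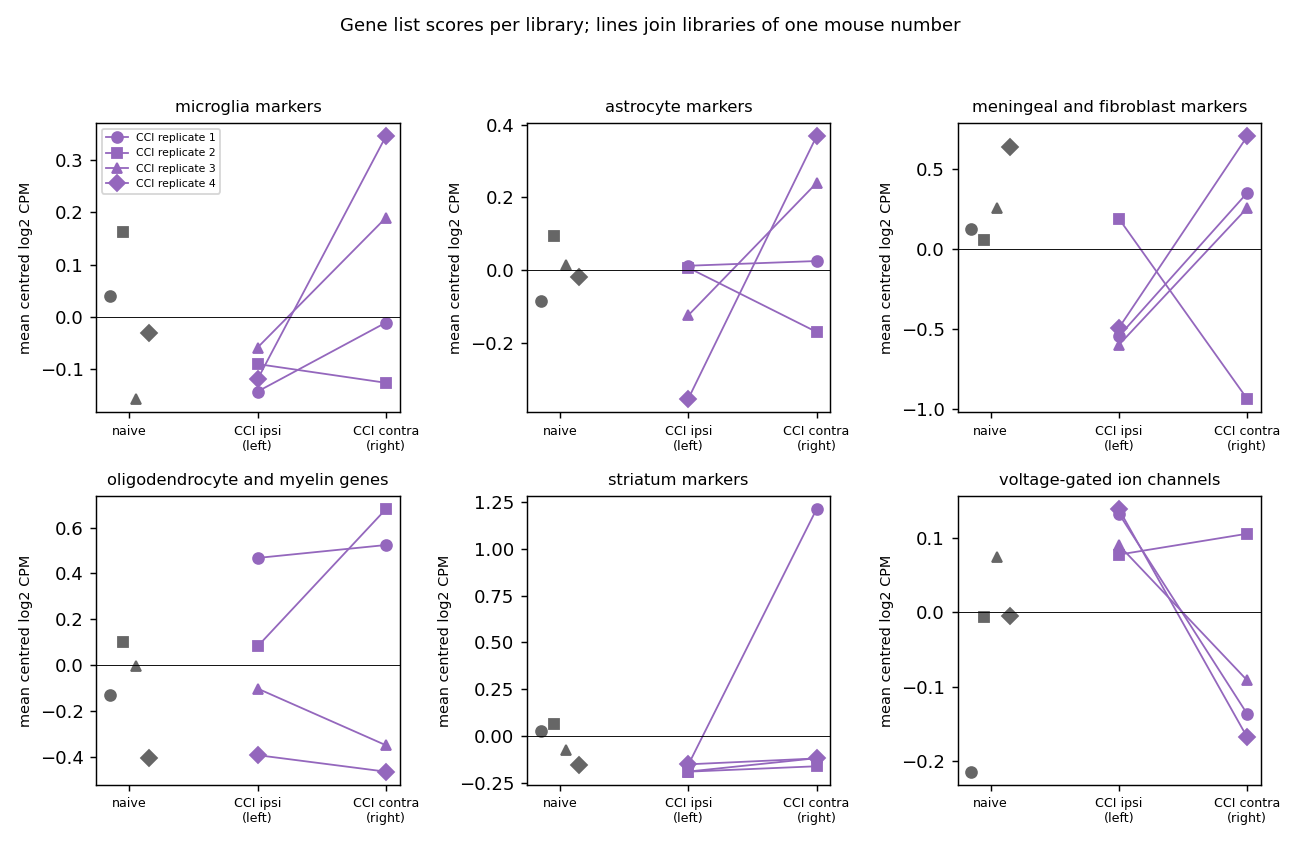
Score per library (mean log2 CPM centred on each gene's mean) for 6 lists, with lines joining the left and right library of one mouse number and naive libraries in grey. The meningeal score is higher on the right in mice 1, 3 and 4 and lower in mouse 2 (0.19 on the left, -0.94 on the right).

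Of 4154 GO and KEGG terms, 66 were called between the sides, 30 higher and 36 lower on the contralateral one, and 0 with an estimated correlation (smallest adjusted p = 0.716 with an estimated correlation). Higher were ribosomal terms (GO: cytosolic ribosome, 71 of 91 genes positive; adjusted p = 0.0120) and matrix terms (GO: collagen trimer, 48 of 67; 0.0317). Lower were KEGG: Synaptic vesicle cycle (45 of 61 negative; 0.0120) and GO: potassium channel complex (50 of 66 negative; 0.0157).

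At an unadjusted p under 0.05 there were 1322 genes between the sides (724 higher, 598 lower, against 790.4 with uniform p values). That fit did not use the pairing of left and right libraries. In edgeR with a mouse block, 725 of 15526 tested genes were at an unadjusted p under 0.05, and the smallest adjusted p was 0.741. The excess over uniform p values was thus not seen in the paired fit. The edgeR count between the sides was 0 of 15808 genes, and limma voom and DESeq2 gave 0 each. The count rested on mouse 2: it became 159 without contralateral 2, and 286 (166 higher, 120 lower) without both libraries of mouse 2, a fit chosen after seeing the data, in which Mfge8 stood at 0.72, Fmod at 1.92, Aqp4 at 0.49 and Gad1 at -0.31. The lists called became 10 without mouse 3 and 7 without mouse 4, also chosen after seeing the data.

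CCI mice were then compared with naive mice as animals, with both hemispheres summed. Wdfy1 again differed by a log2 fold change of 1.03 (SE 0.12). It was joined by Ccdc71 (1.32, SE 0.17), Rsrc1 (0.73, SE 0.10), Pds5a (-0.48, SE 0.07) and Atf2, a stress-responsive transcription factor gene (-0.45, SE 0.06). All 5 had an edgeR adjusted p = 0.0541, just short of the threshold. All but Wdfy1 lay at or near the naive level in part of the CCI libraries, as given below. Oligodendrocyte and myelin genes had a positive fold change in all 22 members (median 0.22) and meningeal and fibroblast markers a negative one in 17 of 18 (-0.18). Both camera calls were lost, with adjusted p = 0.861 and 0.723 with an estimated correlation, and the myelin scores of CCI mice spread widely (SD 0.44, n = 4; exact permutation p = 0.514 against naive mice).

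Next came Eif4h, a translation initiation factor gene (0.48, adjusted p = 0.102), Ube2e2 (0.35), Zmym5 (0.40) and Lmo7 (-0.32), each with adjusted p = 0.151, then Tfap2d (-1.69, adjusted p = 0.181), Lmbr1 (-0.33, adjusted p = 0.219) and the oxytocin receptor gene Oxtr (-0.69, adjusted p = 0.425). Several of these genes took 2 levels among the CCI libraries. Eif4h was at 241 to 247 CPM in ipsilateral 4, contralateral 2 and contralateral 3, beside 243 to 252 CPM in naive libraries, and at 371 to 416 CPM in the other CCI libraries. Pds5a was at 64.2 CPM in contralateral 4, within the naive range of 61.8 to 65.9, and at 41.2 to 45.0 CPM elsewhere. Wdfy1 lay at 50.2 and 49.7 CPM (left and right) in mouse 4 and 52.0 and 54.9 in mouse 1, and at 38.4 and 38.4 in mouse 3 and 39.1 and 34.8 in mouse 2. Adjusted over the list alone Oprl1 (0.39) passed, and over all genes tested 0 list members did.

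Camera called 5 lists at the level of mice. Higher were oligodendrocyte and myelin genes (adjusted p = 0.00896), cytosolic ribosomal protein genes (52 of 82 positive; 0.0371) and glucocorticoid response genes (15 of 18 positive; 0.0399; Zbtb16 0.23, Tsc22d3 0.27). Lower were meningeal and fibroblast markers (0.000127) and blood cell genes (6 of 8 negative; 0.0467). All 5 were lost, with adjusted p = 0.723 to 0.861 with an estimated correlation. The edgeR count was 0 of 16179 genes, limma voom gave 0 and DESeq2 28, among them Wdfy1, Ccdc71, Rsrc1, Pds5a, Atf2, Eif4h, Abi3bp, Tmem260 and Oxtr. At an unadjusted p under 0.05 there were 679 genes (291 higher, 388 lower, against 808.95 with uniform p values). The count became 6 without CCI mouse 1, 3 without CCI mouse 2, 6 without CCI mouse 4, 6 without naive 2 and 1 without naive 3, and the lists called became 3 without CCI mouse 2, CCI mouse 3 or naive 1.

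Both hemispheres were compared with the same naive libraries, which alone makes the results alike. Fold changes of contralateral and ipsilateral against naive correlated by 0.440 across genes, which are not independent replicates. In 20 simulations of unchanged groups set against the shared naive libraries the correlation was 0.445 to 0.547 (mean 0.500). For the overlap, limma on log2 CPM was used in place of edgeR. It gave 627 contralateral and 809 ipsilateral genes at an unadjusted p under 0.05. Their same-sign overlap was 130 genes, against a mean of 168.65 in the simulations and 16.2 for independent lists. The observed correlation and overlap lay below every simulation (lowest 0.445 and 150). Genes varied independently of one another in the simulations, so their range need not hold for these data. When the 2 sides were set against separate naive libraries, the correlation was -0.043 to 0.024 in 6 arrangements. The likeness of the hemispheres was thus no greater than the shared controls give.

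Scores per library passed in no list (0 of 32 in each comparison) after adjustment. Before adjustment 1, 2, 1 and 1 lists (contralateral and ipsilateral against naive, contralateral against ipsilateral, and mice) had the smallest exact permutation p of 0.0286, the floor for 4 against 4 libraries. They were glucocorticoid response genes against naive for the contralateral side and for mice, voltage-gated ion channels and olfactory markers for ipsilateral against naive, and olfactory markers between the sides. Paired by mouse, olfactory markers between the sides had an exact sign-flip p of 0.125, the smallest that 4 pairs allow. For any list to pass after adjustment, at least 19 of the 32 had to reach the floor together, so the count of 0 was nearly fixed beforehand.

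The remaining lists were called in no comparison. With a mouse block, chosen after seeing the data, excitatory neuron markers were also called lower on the contralateral side (camera adjusted p = 0.0381, but adjusted p = 0.539 with an estimated correlation, adjusted within the comparison). With the same block by replicate number against naive, immediate early genes were called higher on the contralateral (camera adjusted p = 0.0148) and ipsilateral side (0.0187), but not with an estimated correlation (adjusted p = 0.844 and 0.720 with an estimated correlation). That block also called oligodendrocyte and myelin genes higher for ipsilateral against naive (0.00713, but adjusted p = 0.818 with an estimated correlation) and left microglia markers uncalled for contralateral against naive (0.0863). Without the block, the smallest camera adjusted p was 0.0607 for heat shock and unfolded protein genes, 0.0702 for excitatory neuron markers, 0.0757 for olfactory markers (Cdhr1 -1.20 and Fabp7 -0.77 for ipsilateral against naive), 0.0803 for glutamate receptors and 0.103 for circadian clock genes. It was 0.182 for immediate early genes, 0.205 for DNA methylation and histone deacetylase genes, 0.217 for choroid plexus and ependyma markers, 0.221 for cytokines and chemokines, and 0.276 for neurotrophic factors. It was 0.415 for sex-linked genes, 0.497 for perineuronal net genes, 0.682 for inhibitory interneuron markers and 0.766 for opioid and endocannabinoid genes. Test direction, median and mean differed in sign for some uncalled lists, such as immediate early genes between the sides (median 0.05, mean 0.02, test lower) and monoamine receptors for contralateral against naive (median -0.03, mean 0.01, test lower).

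Of 14557 genes, 142 took 2 well separated levels across the 12 libraries, and 0 of them parted all CCI from all naive libraries; the examples here were chosen after their values were seen. Ndst4 is among them, low in 7 of the 8 CCI libraries and at 11.3 CPM in contralateral 4. The potassium channel gene Kcna2 was at 1.84 CPM in naive 1 and at 225 to 342 CPM in the other libraries. The glutamate transporter gene Slc1a2 was at 295 to 510 CPM in 7 libraries and at 2432 to 2786 CPM in 5. Tmed2 was at 0.44 to 1.09 CPM in ipsilateral 2, contralateral 2 and ipsilateral 3 and at 24.4 to 30.1 CPM elsewhere, and Erbb4 at 18.6 CPM in contralateral 3 and 78.1 to 101 CPM elsewhere. Kcna2 stands on the list of voltage-gated channels and Slc1a2 on that of astrocytes; without genes of 2 levels, chosen after seeing the data, camera called 7 lists for contralateral and 9 for ipsilateral against naive, 15 between the sides and 4 for mice.

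**Figure D3:**
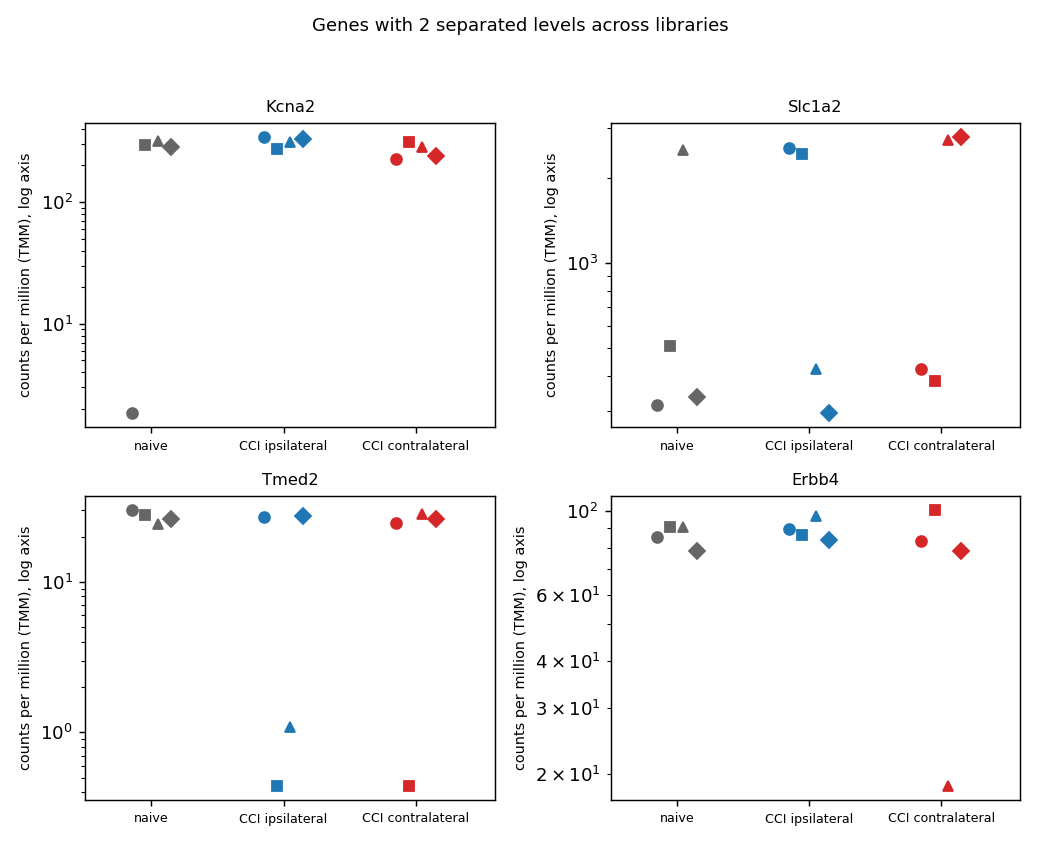
Levels of Kcna2, Slc1a2, Tmed2 and Erbb4 in each of the 12 libraries, in CPM on a log axis, by group. Kcna2 lies at 1.84 CPM in naive 1 and at 225 to 342 CPM in all others.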

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

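The test on the share of neurons was chosen only after the result was seen, and the exchange test of mouse 2, whose bounds were set before its own result, was prompted by gene counts and meningeal scores that rested on mouse 2.

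Microglia markers were called higher than naive on the contralateral and lower on the ipsilateral side by camera, and the direct test between the sides gave a camera adjusted p of 3.65e-06. None of these calls held (adjusted p = 0.823 for each side against naive and adjusted p = 0.723 between the sides, with an estimated correlation), and scores per library gave exact permutation p = 0.429, 0.200 and 0.114. Within the same lists, the meningeal and fibroblast score of ipsilateral 2 stood apart at 0.190, against -0.60 to -0.49 in the other ipsilateral libraries, and contralateral 2 had the lowest score of its side (-0.94).

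For this left-right pattern 3 explanations were tested. Contralateral 1, which held striatum genes (score 1.21), is argued against as the sole source, since 15 of the 16 lists kept their call and direction without it. An exchange of the left and right libraries of mouse 2 stays open: of 200 genes chosen in mice 1, 3 and 4, 72.5% went the opposite way in mouse 2, short of the 75% set beforehand, and mice 1, 3 and 4, each held out from the other 2, went the same way in 68%, 71% and 74%. With these 2 libraries exchanged, 225 genes passed in edgeR against 0 as labelled. Lists called by camera, adjusted within the comparison, went the other way, with 11 against 17 as labelled. Of the 16 lists, 8 turned in mouse 2 (-0.02 for interferon response genes to -1.13 for meninges among those higher on the right) and 5 kept their direction, with scores between -0.07 and 0.03, and a mouse whose dissection took in more meninges on the left could give the same values. A lower share of neurons on the right, raising all other cell types alike, cannot be told apart from separate changes, because 4 mice allow no exact p below 0.125, the value found; a true difference between hemispheres under nerve injury also stays open, since each naive mouse gave 1 library of an unstated side.

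Of 327 groups of 4 libraries tested for a library far from the other 3, 27 had one, where chance gives about 16.35. In contralateral 1, the striatum score was 1.21, Adora2a 15.2 CPM and Drd2 8.77 CPM, and it also stood apart in Tmem35 (55.5 CPM) and Zbtb16 (51.2 CPM). Contralateral 4 stood apart in Ndst4 (11.3 CPM) and Pds5a (64.2 CPM). Ipsilateral 4 stood apart in Pds5a (41.2 CPM), Ccdc71 (6.20 CPM), Eif4h (247 CPM) and Gja1 (115.0 CPM). Ipsilateral 2 did so in Fmod (4.95 CPM), Tsc22d3 (35.1 CPM) and Olfml3 (9.07 CPM). Ipsilateral 1 did so in Zbtb16 (52.5 CPM) and Htr2c (14.1 CPM), and ipsilateral 3 in its share of mitochondrial counts (7.59%). Among naive libraries, naive 1 stood apart in Tfap2d (1.67 CPM) and Drd2 (1.62 CPM), naive 2 in Fkbp5 (23.3 CPM), naive 3 in Wdfy1 (19.9 CPM) and C1ql1 (4.96 CPM), and naive 4 in Scn3b (27.5 CPM) and Ogn (2.34 CPM). Total counts were highest of their group in ipsilateral 2 (20.6 M) and lowest in contralateral 2 (16.1 M).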

How the results depend on the processing

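The fits without genes of 2 levels, without overlapping genes, without a whole mouse and the list tests with a replicate block were chosen after seeing the data. The count of 0 genes in each comparison was kept with RLE factors, a filter of 1 CPM in 4 libraries, limma voom, a cell type covariate and without overlapping genes. It moved, the cause untested, with DESeq2 (3 contralateral against naive, 9 ipsilateral against naive, 28 mice), with library size only (4, mice), with no filter (5, mice), with the 2 compared groups alone (1 contralateral and 7 ipsilateral against naive) and with the mouse as a random block in limma (1). A block for the replicate number, though naive libraries are of other mice, gave 2 genes for contralateral and 6 for ipsilateral against naive, and 0 between the sides. Without the 142 genes of 2 levels, mice gave 4, Wdfy1, Pds5a, Rsrc1 and Atf2 (edgeR adjusted p = 0.0477 each). None of these 4 is among the 142. The fit therefore did not remove genes such as Pds5a and Rsrc1, which lay at the naive level in some CCI libraries. Unadjusted p under 0.05 with a 2-fold change held for 23, 48, 53 and 23 genes (contralateral and ipsilateral against naive, between the sides, mice). Leaving out 1 library or mouse gave 0 to 2, 0 to 1, 0 to 159 and 0 to 6 genes, and leaving out both libraries of mouse 2 gave 286 between the sides (0 without mouse 1, 3 or 4). Lists called fell to 0 in all comparisons with an estimated correlation, with fry and with fry in mixed direction. Leaving out 1 library or mouse moved them to 4 to 12 for contralateral against naive and 3 to 6 for mice, and between the sides to 10 without mouse 3 and 7 without mouse 4 (14 without mouse 1 or 2). With a replicate block camera called 6, 11 and 17 lists (contralateral and ipsilateral against naive, between the sides). Scores were at 0 lists with means or medians, which shows no stability, since at least 19 lists at the smallest possible p are needed to pass. For the named genes, 5645 of 5929 alternatives kept direction and side of the threshold, 101 passed it, and 183 changed sign, all of them of results with an unadjusted p of 0.05 or more. Depth limits genes near the floor such as Oprm1 and Tbx15. In simulated data with 4 libraries per group 65% to 66% of 1.5-fold changes were recovered between libraries. That share holds for many changes planted at once and need not hold for these data.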

Other observations

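The tests on overlapping gene models, on the share of libraries at the high level and on the Wdfy1 levels of left and right libraries were chosen only after the results were seen, and the substrain test, set before its own result, was prompted by the Wdfy1 levels.

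Immediate early genes, which respond to neuronal activity, varied more within groups than between them. Scores of the left and right library were -0.34 and -0.38, -0.06 and -0.20, 0.20 and 0.22, and 0.45 and 0.54 in the CCI mice, and -0.82, -0.25, 0.04 and 0.60 in the naive mice of the same numbers, so that libraries with one number were alike in all 3 groups, without a tested explanation. With a block for the number, chosen after seeing the data, camera called the list higher against naive on the contralateral (adjusted p = 0.0148) and ipsilateral side (0.0187), and both calls were lost (adjusted p = 0.844 and 0.720 with an estimated correlation). Fos ranged from 8.31 to 80.1 CPM and Arc from 47.7 to 379 CPM among the naive libraries alone.

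The genes of smallest p between CCI and naive mice may be read as an effect of injury, but the design cannot part injury from any other difference between the mice of the groups. These genes lie on several chromosomes (such as Wdfy1 on 1, Atf2 on 2 and Rsrc1 on 3), so 1 segment could not hold them all. Segments with several changed genes are argued against as the common source, since 2.95% of 474 neighbours within 2 Mb were at an unadjusted p under 0.05 (95% exact interval 1.62 to 4.91), against 4.20% of all genes. The share pools the neighbours of all these genes, so it cannot decide on a segment around 1 of them, such as Wdfy1. Meningeal tissue stays open. With the meningeal score as covariate, the median fold change of these genes was 0.964 of its size (0.764 for Oxtr to 1.11 for Lmbr1). The test cannot decide, because genes of smallest p in the same fit vary little within groups. Their fold changes were therefore likely to keep their size with any covariate. A difference between C57BL/6 substrains, if the mice are of that strain, stays open: the log2 fold change of Nnt, which carries a deletion in one substrain, was -0.36 (SE 0.19), with a lower 95% limit of 0.797 in absolute size, beside Ide at 0.03, and Entpd4 was not among the tested symbols. Left and right Wdfy1 levels lay as close as coded in 2 of 24 pairings, too many to show a level fixed per mouse.

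Genes with 2 levels are in part a candidate artifact of counting, since 55.6% of the 142 overlapped another gene against 41.2% of the others (odds ratio 1.79, Fisher's exact p = 0.00078). The set is mixed, and in some of its genes, such as Kcna2, Erbb4, Adora2a and Drd2, only 1 library stood apart. For Adora2a and Drd2 it was contralateral 1, which held striatum genes, so the 142 need not have 1 source. Nerve injury is argued against as the source of the pattern as a whole. Of 495 choices of 4 libraries, 378 differed as much from the other 8 in the share at the high level as naive from CCI libraries (mean 0.194, largest other 0.238). Genes with only 1 library apart cannot follow the groups but enter this mean, so it says little about the other genes alone. Injury stays open for Ndst4, the 1 gene that parted ipsilateral from naive. The count of 0 genes parting all CCI from naive libraries decides nothing, since all 495 choices reach it (highest other 1). For a fixed difference between mice, 23 of 24 pairings had levels as concordant between left and right libraries as the coded pairing. The coded pairing agreed in 67.3% of levels, the median of the others in 68.7%. This argues against it only if libraries with the same number are of the same mouse. The pairing rests on the library codes alone, so the test does not decide. Reads moving between overlapping gene models stay open: 59.8% of 204 pairs of a gene and its overlapping partner moved in opposite ways, such as Zbtb9 and Ggnbp1, but genes recur among the pairs, and per locus it was 66.7% of 39 (95% exact interval 49.8 to 80.9).

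Other splits of the same libraries into groups of 4 (35 each) were set beside the counts. For genes past the threshold the splits decide nothing, since the count was 0 in each comparison and all 35 splits reach it (highest other 1 for contralateral against naive, 2 for ipsilateral against naive, 225 between the sides and 1 for mice). The count of 225 came from the split that exchanges the left and right of mouse 2, which points to a structure of the libraries. For genes at an unadjusted p under 0.05, the count for ipsilateral against naive was reached by 1 split alone, the real one (763, highest other 742). By the rule set beforehand, a share of splits under 0.05, this count goes against chance. Yet all splits of this comparison lay under the 790.4 that uniform p values give. Several counts were compared with splits in this way, and 1 of 35 is the smallest share possible, so chance is not excluded. Nor is it for contralateral against naive (597, highest other 2537, reached by 22), between the sides (1322, highest other 2618, reached by 8) or mice (679, highest other 1992, reached by 15). For lists, adjusted within the comparison, the count between the sides was reached by 1 split, the real one (17, highest other 16), but the 8 splits with 1 library of each mouse on either side (highest other 13) are too few for a share under 0.05. Chance is not excluded for contralateral against naive (6, highest other 17, reached by 21), ipsilateral against naive (9, highest other 12, reached by 5) or mice (2, highest other 12, reached by 30).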
